A study of Homo sapiens with 4 samples.

How the data were processed

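Poly(A)-selected RNA of Y79 cells was sequenced from 2 BPA libraries and 2 DMSO libraries after 48 h, made with Illumina TruSeq reagents per the labels' protocols. Per the submitters' processing notes, CASAVA, Trim Galore, STAR 2.7, limma, edgeR 3.28.0 and DESeq2 1.26.0 were used with genome build GRCh38. Their order, the read counter, the annotation release and whether strand was used are not given in the sources used here. The authors deposited raw read counts and FPKM values (fragments per kilobase of transcript, scaled by library), both for 227368 Ensembl transcripts. The planned design assumed counts per gene, so transcript counts were summed per gene, and the transcript test and the sums over transcript classes are additions made after the data were seen.

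The deposited counts were checked against the GENCODE 29 annotation (GRCh38). Of these transcripts, 205950 matched its identifiers and 21418 did not, and the matched ones held 99.2% to 99.4% of the counts of each library. Unmatched transcripts stayed out of the gene sums but entered the transcript test. Transcripts with no base free of other transcripts, 67315 in all, held 0.414% of counts, and 1.68% of them had any count. Transcripts with at least 50 bases free of other transcripts on both strands held 99.2%. Of transcripts free of others on their own strand alone, 4.28% had a count. The counts therefore behave as reads that fall on 1 transcript without regard to strand. A gene's sum reflects the parts of its isoforms that overlap nothing else, so a gene with many isoforms is read through few bases, often introns, and overlapping antisense genes cannot be told apart. Of the 12063 genes tested, 2366 drew most of their counts from retained-intron transcripts. Reads that match several places seem to be counted at each. The lincRNAs FP236383.2 and FP236383.3 had 9692 and 9686 counts in DMSO replicate 1 and 24719 and 24716 in BPA replicate 2, so paralogs and pseudogenes are uncertain. The deposited FPKM values were 0 exactly where the count was 0. They follow the counts divided by length and 1 factor per library, relative to DMSO replicate 1 1.10, 1.32 and 1.34, while the library totals relative to it were 1.10, 0.950 and 0.999. FPKM served only as an alternative.

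Gene symbols came from a gene name table by gene identifier for 58201 of 58654 matched genes. Genes were kept by filterByExpr with a minimum count of 10, scaled by TMM (CPM are counts scaled to a library of 1e6) and tested with the edgeR 4.0.16 quasi-likelihood test on group alone, in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.0795. SE values come from the same test. For 36 fixed gene lists, camera of limma 3.58.1 was run with a preset correlation of 0.01, two-sided, over the 31 lists with at least 5 measured genes, and again with the correlation estimated. Estimating it left 0 of the 6 calls, with 4 of 31 lists at an unadjusted p under 0.05. The estimates for the ATF4, circadian clock and histone lists were 0.0019, -0.0511 and -0.1325. These lie below the preset, so a higher correlation did not cost those calls. For the cholesterol, heat shock and mitochondrial lists they were 0.0393, 0.3407 and 0.4981. With estimation camera also takes its degrees of freedom from the libraries, and so few libraries make it a much weaker test. Counts of members are given over all genes tested and adjusted over the list alone. Retained-intron and protein-coding reads of the same gene were compared by an interaction term with library as a block, in genes with a mean count of at least 20 in both classes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The samples, tests, lists, naming rule and most alternatives were fixed before the data were examined.

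The named genes are, first, the 12 with the largest rises and the 12 with the largest falls among genes past the threshold, with both groups separate in CPM, a mean count of at least 100 in the higher group and a symbol that is neither a clone name nor a pseudogene. Up to 4 passing members of each described list, by smallest adjusted p, or 2 where none passed, were added, together with ESR1, ESR2, ESRRG, GPER1, AHR, MYCN, RB1, CRX, RCVRN and ARR3 as checks. A few further list members and transcripts are named after their values were seen. XIST and Y-linked genes are not named, and the values of some genes that this rule takes are not reported here.

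On simulated counts with the means of these libraries, the gene test called 65 of 100 genes changed 2-fold and 23 of 100 changed 1.5-fold, with 3 false calls among 11528 genes. The transcript test called 47 of 100 and 13 of 100 with 1 false call among 15959, and the test of retained-intron against protein-coding reads called 63 of 100 at 2-fold with 3 false calls among 799 genes. Camera called the planted list and 0 of 30 random lists. At these depths, 2930199 to 3382986 counts per library, the simulated changes under 2-fold were often missed. In the data far more genes passed, 2750 higher and 2832 lower of 12063. The adjusted threshold is then less strict, so the simulated rates do not carry over. The simulation of retained-intron reads used a fixed dispersion that was not taken from the data. Alternatives covered the test (DESeq2 1.42.0, limma-voom, edgeR exact test, glmTreat at 1.5-fold), scaling, filters on low counts, FPKM with pseudocounts of 1 and 0.1, a replicate block, leaving out each library, and, added later, protein-coding transcripts only, no retained-intron transcripts, and no mitochondrial genes, pseudogenes or near-identical lincRNAs. All columns of the files were assigned to samples by their names.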

Results

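Messenger RNA was measured by sequencing in Y79 cells, an established line from a human retinoblastoma, a childhood tumour of the retina. Cells exposed for 48 h to bisphenol A (BPA), a monomer of polycarbonate plastics and epoxy resins that binds estrogen receptors weakly, were compared with cells given the solvent dimethyl sulfoxide (DMSO). Each group held 2 libraries. The labels give the BPA dose as 40 mM, and nothing else in the sources used here checks that unit. The 4 libraries held 3084393 and 3382986 counts in the DMSO group and 2930199 and 3082798 in the BPA group. The labels do not say that the libraries of a group came from separate cultures, so the p-values below measure only the spread between these samples, which may be technical. The gene counts of replicates differed by more than independent sampling would give (chi-square per degree of freedom 3.31 for DMSO and 3.25 for BPA), a measure that reads counted at several copies also raise.

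The comparison asks which genes differ in expression between BPA-treated and solvent-treated retinoblastoma cells. Heat shock genes, among them HSPA6, HSPA1A and HSPA1B, were among the largest rises in BPA, and all 13 mitochondrially encoded mRNAs fell. In the lists of ATF4 signalling and the circadian clock 16 of 27 and 9 of 14 measured genes rose, and 6 of 8 replication-dependent histone genes fell. These list calls were lost when camera estimated the correlation (adjusted p = 0.334 for each), though the estimates lay below the preset of 0.01. Retinal genes went both ways, with RCVRN and ATOH7 lower and ONECUT2 and SIX3 higher. Of 12063 genes tested, 2750 were higher and 2832 lower in BPA (edgeR quasi-likelihood test, adjusted p under 0.05), of which 1321 and 1180 changed by at least 2-fold. The first principal component held 81.0% of the variance and separated the groups, and log expression correlated across genes, which are not independent replicates, at r = 0.976 between the DMSO libraries, 0.985 between the BPA libraries and 0.901 to 0.915 between groups. These directions are relative to the typical gene: scaled by library totals alone, the median of all genes shifted by 0.41 on the log2 scale and the calls became 5080 higher and 1251 lower. DESeq2, which was run on all 30316 genes with a count and with its own filter on low counts, so that test and filter changed together, called 1268 higher and 1263 lower.

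The largest rise among called genes with a mean count of at least 100 in the higher group was that of HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526910, GRCh38), a stress-inducible HSP70 chaperone, from 1.64 ± 0.35 to 148 ± 29.7 TMM-scaled CPM (SD, n = 2), a log2 fold change of 6.47 ± 0.26 (SE, adjusted p = 1.00e-13). HSPA1B (ENSG00000204388, chromosome 6, 31827735 to 31830255) rose from 49.5 ± 14.9 to 892 ± 242 CPM and HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946) from 13.1 ± 7.15 to 270 ± 87.3 CPM (SD, n = 2), with log2 fold changes of 4.17 and 4.38. These paralogs are nearly identical, so the division of reads between them is uncertain. GLIPR1, a gene of the CAP protein family, rose by 4.91, and SERPINH1, a collagen chaperone of the endoplasmic reticulum, by 4.08 on the log2 scale. HSP90AB1, a cytosolic HSP90 gene, rose by 3.33, TINCR by 3.25 and OVGP1, an oviductal glycoprotein gene, by 3.10. HSP90AB1 had only 10 and 9 counts in DMSO and 130 and 108 in BPA, with 86.8% of its reads in the same transcript. For the remaining 4 of the 12 largest rises the reads lay mostly outside protein-coding transcripts. HSP90AA1 rose by 4.42 with 61.3% of its reads in retained-intron transcripts. Its protein-coding transcripts held 4.05% of its reads and alone had a log2 fold change of 0.27 (adjusted p = 0.430). HSPH1 (log2 fold change 3.58), an HSP110 chaperone, and TECR (3.60), a fatty acid elongation enzyme, were read almost only through retained-intron transcripts. HSPB1 (3.87), a small heat shock protein, was read mostly through a transcript annotated for nonsense-mediated decay. TECR (chromosome 19, 14517085 to 14565980) overlaps the heat shock gene DNAJB1 (14514770 to 14529770). The counts follow no strand, so the TECR rise may hold reads of DNAJB1.

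Among the 12 largest falls were DBH (ENSG00000123454, chromosome 9, 133635348 to 133659344), which encodes the enzyme that makes noradrenaline from dopamine, and its antisense gene DBH-AS1 (ENSG00000225756, chromosome 9, 133654586 to 133657313). DBH fell from 86.8 ± 16.2 to 6.35 ± 1.14 CPM (SD, n = 2), a log2 fold change of -3.76 ± 0.21 (SE, adjusted p = 1.42e-11), and DBH-AS1 by 3.88. The counts follow no strand, so reads of this overlapping pair cannot be told apart. TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600), a glucose-responsive inhibitor of thioredoxin, fell from 321 ± 11.7 to 47.6 ± 4.87 CPM (SD, n = 2), a log2 fold change of -2.75 ± 0.12. APOBEC2, a member of the cytidine deaminase family, had a log2 fold change of -3.25, PCLAF, a PCNA-binding protein of replicating cells, of -2.40, and the transcription factor gene TCF15 of -2.33. The long noncoding RNA genes LINC03053, TMPO-AS1 and LINC02078 had log2 fold changes of -2.96, -2.68 and -2.56, and the strand limit covers TMPO-AS1 too. The mitochondrial genes MT-TI (a transfer RNA, -2.42), MT-CO3 (-2.35) and MT-CYB (-2.28) completed the 12.

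**Figure D1:**
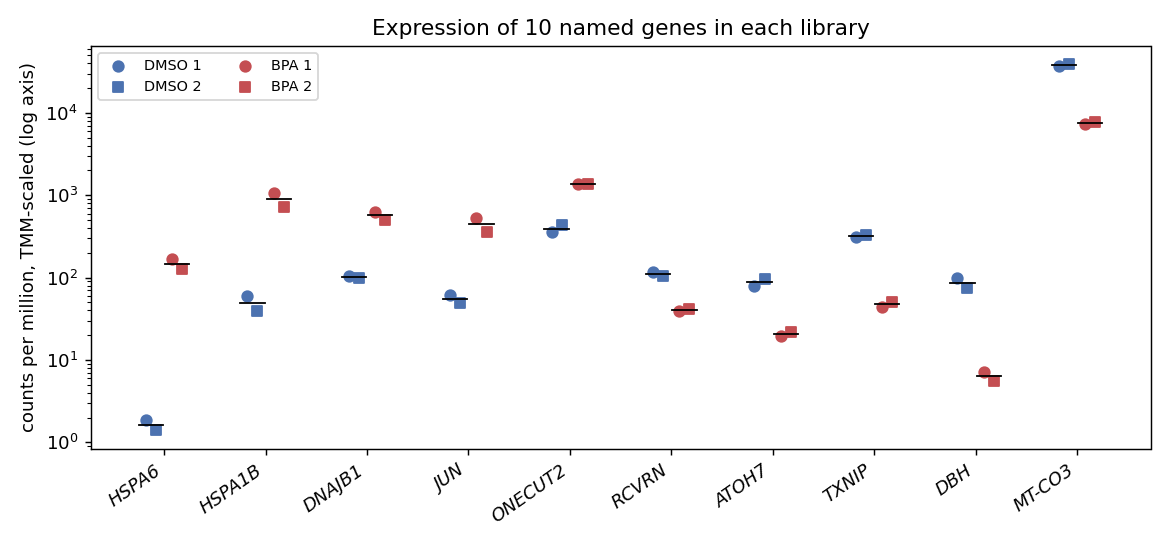
Expression of 10 named genes in each library, as TMM-scaled CPM on a log axis, with DMSO in blue, BPA in red, replicate 1 as circles, replicate 2 as squares and group means as black lines. HSPA6 had a mean of 1.64 in DMSO and 148 in BPA.

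Of the 14 measured members of the heat shock list, which does not hold HSPA6, 11 rose, 2 fell and 1 did not pass (the same counts adjusted over the list alone). The list was higher in BPA in the set test (camera, adjusted p = 5.47e-22), with a median log2 fold change of 2.38. The call was lost with an estimated correlation (adjusted p = 0.334). DNAJB1, a co-chaperone of HSP70 read through protein-coding transcripts, rose from 280 and 283 to 2117 and 1739 counts (log2 fold change 2.48 ± 0.12, adjusted p = 1.07e-12). HSPA4, an HSP110 family chaperone, had a log2 fold change of -1.09 and DNAJA1, an HSP70 co-chaperone, of -0.58, and both fell. BAG3, a co-chaperone, had a log2 fold change of 0.35 and did not pass (adjusted p = 0.493). In 6 of the 14 members most reads lay in retained-intron transcripts. With protein-coding transcripts alone, 5 of 9 members rose and 2 fell, with a median of 1.71, and the list still passed.

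Genes of ATF4 signalling and the amino acid response rose in 16 of 27 measured members and fell in 2 (the same counts adjusted over the list alone; camera adjusted p = 3.57e-05, and adjusted p = 0.334 with an estimated correlation). PPP1R15A, a phosphatase subunit that restores translation after stress, rose by 1.86 ± 0.13 (SE, adjusted p = 2.36e-10), and the alanyl-tRNA synthetase gene AARS1 by 1.29. SLC7A11, the cystine transporter subunit, rose by 1.14 and the seryl-tRNA synthetase gene SARS1, read only through noncoding isoforms without a retained intron, by 1.07. Endoplasmic reticulum chaperone and unfolded protein response genes rose in 7 of 20 members and fell in 1 (6 and 1 adjusted over the list alone), with no call for the list (camera adjusted p = 0.104). That list passed without DMSO replicate 2 (adjusted p = 0.0446), with protein-coding transcripts only (0.0450) and without retained-intron transcripts (0.0436), within a range of 0.0436 to 0.503 over its alternatives. Its members SEL1L, of the degradation machinery, and HSPA5, the main chaperone of that compartment, rose by 1.10 and 0.78. Cholesterol and isoprenoid synthesis genes rose in 10 of 19 members and fell in 1, PMVK (the same counts adjusted over the list alone). SC5D and CYP51A1, enzymes of late sterol synthesis, rose by 1.44 and 1.62, and HMGCS1, read mostly through retained-intron transcripts, by 2.27. That list passed at adjusted p = 0.0214, but not with an estimated correlation (adjusted p = 0.503), nor with protein-coding transcripts only or among genes of at least 50 counts in 2 libraries. JUN, an immediate early transcription factor gene, rose from 55.5 ± 9.06 to 444 ± 115 CPM (SD, n = 2, adjusted p = 3.97e-12 in edgeR). Its list had 4 rises and 1 fall among 12 members (the same counts adjusted over the list alone) and no call (camera adjusted p = 0.0871). With a replicate block the list passed (camera adjusted p = 0.0263). It passed without DMSO replicate 1 (adjusted p = 0.0052), without BPA replicate 2 (0.0388) and without retained-intron transcripts (0.0436), within a range of 0.0052 to 0.503 over its alternatives.

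All 13 mRNAs encoded by the mitochondrial genome, which specify respiratory chain and ATP synthase subunits, fell (camera adjusted p = 9.02e-38, and adjusted p = 0.334 with an estimated correlation; 13 falls adjusted over the list alone). Their median log2 fold change was -1.64, and their share of all counts was 27.3% and 28.1% in the DMSO libraries and 10.7% and 11.2% in the BPA libraries. MT-CO3 (chromosome M, 9207 to 9990), a cytochrome oxidase subunit, went from 38090 ± 1191 to 7469 ± 271 CPM (SD, n = 2), a log2 fold change of -2.35 ± 0.08. MT-ATP6 and MT-ATP8, ATP synthase subunits, had log2 fold changes of -2.22 and -2.07. The mitochondrial rRNA gene MT-RNR2 had a log2 fold change of -0.82 (adjusted p = 4.00e-08) and MT-RNR1 of -0.19 (adjusted p = 0.191). Of 36 nuclear genes of the respiratory chain, 9 rose and 10 fell (11 and 10 adjusted over the list alone; camera adjusted p = 0.890, in the upward direction), with a median of -0.05 that was 0.36 under library totals. In 16 of the 36 most reads lay in retained-intron transcripts, and with protein-coding transcripts only, 3 of 21 rose and 10 fell (median -0.34), with camera in the downward direction and no call. Among them NDUFA1, of complex I, fell by 0.92. ATP5F1A, of ATP synthase, rose by 1.05 with 88.8% of its reads in retained-intron transcripts, and with protein-coding transcripts alone its log2 fold change was -1.10.

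**Figure D2:**
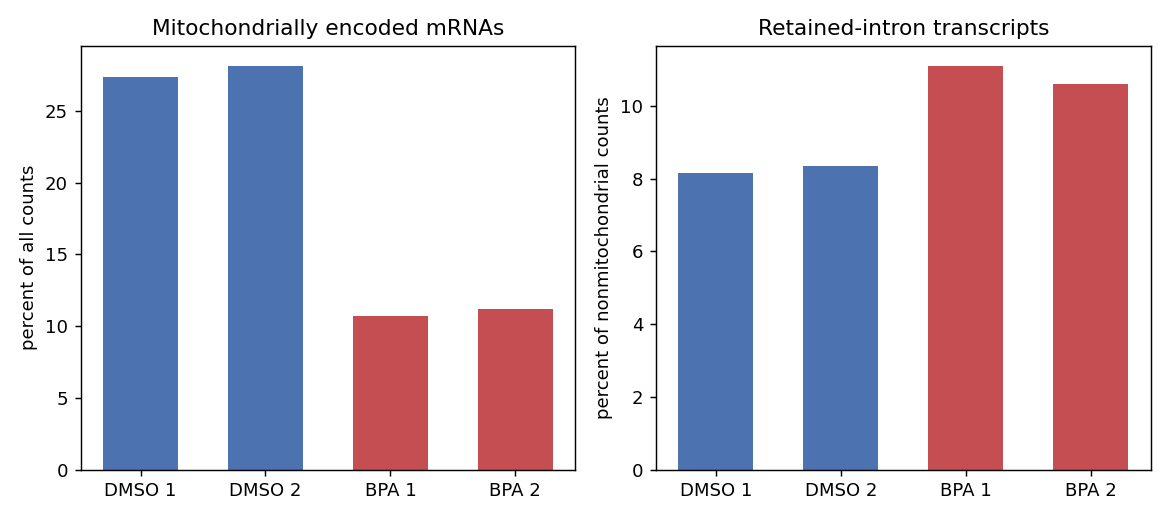
Share of counts in 2 transcript classes, one bar per library, DMSO in blue and BPA in red. The left panel gives mitochondrially encoded mRNAs as a percent of all counts (27.3, 28.1, 10.7 and 11.2), and the right panel retained-intron transcripts as a percent of nonmitochondrial counts (8.16, 8.33, 11.1 and 10.6).

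Circadian clock genes rose in 9 of 14 measured members and fell in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 0.000257, and adjusted p = 0.334 with an estimated correlation). NR1D1 and NR1D2, nuclear receptors that repress clock genes, rose by 1.46 ± 0.14 and 1.04 ± 0.10 (SE), and the related receptor genes RORA and RORB rose by 1.13 and 0.86. Replication-dependent histone genes, expressed in S phase, fell in 6 of 8 members and rose in 0 (8 falls and 0 rises adjusted over the list alone; camera adjusted p = 0.000399, and adjusted p = 0.334 with an estimated correlation), but too few members were left to test it among genes of at least 50 counts. H1-2, a linker histone, fell by 1.55 ± 0.11 (SE, adjusted p = 3.45e-10) and H2BC8 by 1.40. DNA replication genes fell in 11 of 30 members and rose in 7 (the same counts adjusted over the list alone; camera adjusted p = 0.115), with a median of -0.25 that was 0.16 under library totals. Mitosis genes fell in 12 of 26 members and rose in 5 (13 and 6 adjusted over the list alone; camera adjusted p = 0.262), with a median of -0.34 that was 0.07 under library totals. CDC6, which loads the replicative helicase, fell by 1.56 ± 0.13 (SE). Ribosome biogenesis genes fell in 10 of 23 members and rose in 5 (the same counts adjusted over the list alone; camera adjusted p = 0.0740), with a median of -0.17 that was 0.24 under library totals. The lists of DNA replication and of ribosome biogenesis genes passed as lower with protein-coding transcripts only and without retained-intron transcripts, and the latter list also without DMSO replicate 2 (adjusted p = 0.0485, in a range of 0.0037 to 0.503 over its alternatives).

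**Figure D3:**
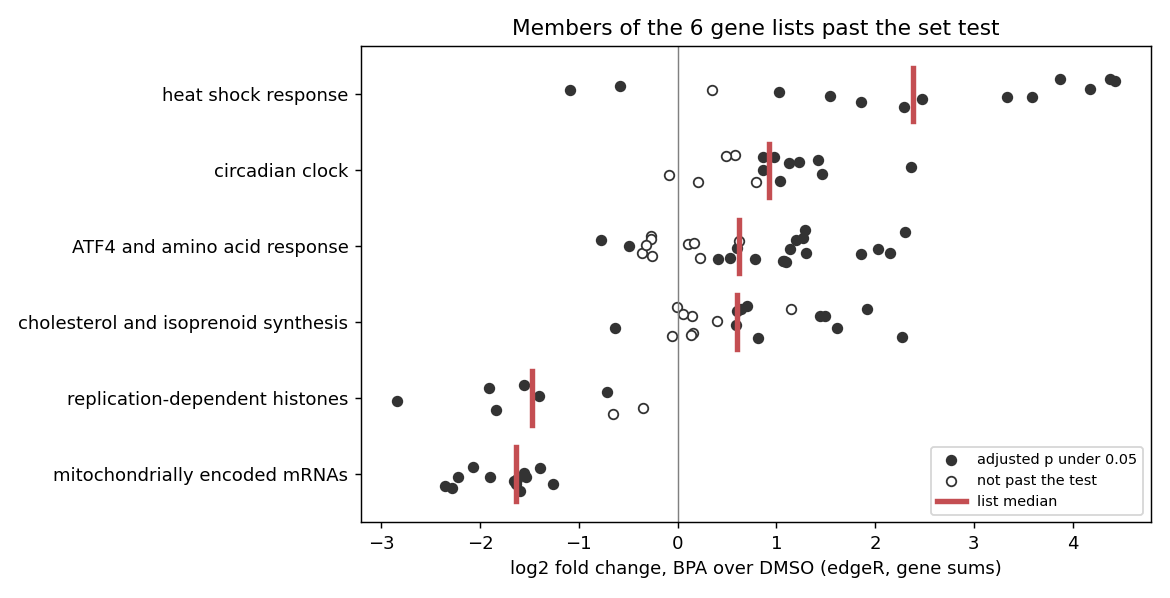
Log2 fold changes (BPA over DMSO) of the members of the 6 gene lists that passed the set test. Each point is 1 gene, filled where its adjusted p was under 0.05 and open otherwise, vertical position within a list has no meaning, and red lines are list medians (2.38 for heat shock, -1.64 for mitochondrially encoded mRNAs).

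Photoreceptor genes fell in 8 of 23 measured members and rose in 3 (the same counts adjusted over the list alone; camera adjusted p = 0.216), with a median of -0.38 that was 0.03 under library totals. RCVRN, recoverin, a calcium sensor of photoreceptors, fell from 309 and 299 to 131 and 144 counts (log2 fold change -1.44 ± 0.13, adjusted p = 2.32e-08). GNGT1, a rod transducin subunit, had 50 and 65 counts in DMSO and 4 and 2 in BPA (log2 fold change -4.50 ± 0.40). THRB, a thyroid hormone receptor of cone development, rose by 1.14 ± 0.19 (SE). ARR3, cone arrestin, had 12 and 16 against 4 and 4 counts (log2 fold change -2.07, adjusted p = 0.002), a call lost with DESeq2. CRX, the photoreceptor transcription factor, had 16 and 17 against 13 and 16 counts, 66.1% of them in a retained-intron transcript, and did not pass (adjusted p = 0.309). Retinal progenitor and neurogenic genes fell in 7 of 12 members and rose in 3 (the same counts adjusted over the list alone; camera adjusted p = 0.262), while under library totals 5 fell and 5 rose and the median went from -0.77 to -0.36. ATOH7, needed for ganglion cell formation, fell by 2.08 ± 0.16 and NES, the intermediate filament nestin, by 2.62 ± 0.27, while ONECUT2, a factor of early retinal neurons, rose by 1.80 ± 0.10 and SIX3, an eye field factor, by 0.79 ± 0.10 (SE). MYCN, the oncogene amplified in this line, had 1217 and 400 counts in DMSO and 3210 and 2128 in BPA, a log2 fold change of 1.40 ± 0.28 (SE, adjusted p = 0.000423). The value was 2.50 without DMSO replicate 1 and 0.78 without DMSO replicate 2, and the call was lost with DESeq2, without a filter on low counts and on FPKM. RB1, the tumour suppressor lost in retinoblastoma, had 8 and 13 against 20 and 14 counts (adjusted p = 0.459).

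Of 17 receptors proposed for BPA, 6 were measured, 4 rose and 0 fell (the same counts adjusted over the list alone), and the list did not pass (camera adjusted p = 0.108). ARNT, a partner of the aryl hydrocarbon receptor, rose by 1.84 ± 0.26 and THRA, a thyroid hormone receptor gene, by 0.64 ± 0.16 (SE), beside THRB, which is on this list too. THRA lost its call with DESeq2 and on FPKM. ESRRA rose by 0.93, a call lost without DMSO replicate 2 (0.46), without BPA replicate 2 (0.91), with DESeq2 and on FPKM. The call was also lost without a filter on low counts, with protein-coding transcripts only (0.79) and without retained-intron transcripts (0.76). Without DMSO replicate 1 the value was 1.57. The estrogen receptor gene ESR2 had 15 and 23 against 9 and 17 counts and did not pass (log2 fold change -0.84, adjusted p = 0.0917). It passed without DMSO replicate 1 (-1.06), and was -0.46 and -1.33 without BPA replicate 1 and 2. ESR1 (3, 11, 6 and 8 counts) and ESRRG (2, 5, 2 and 1) were too low to test. No count of GPER1 or AHR was seen in any library, which allows up to 0.887 to 1.02 CPM per library, for counting error only. A gene whose bases all overlap other transcripts could also have no count, and this was not checked for either gene. Estrogen response genes rose in 3 and fell in 4 of 12 members (the same counts adjusted over the list alone; camera adjusted p = 0.849), with a median of -0.06 that was 0.34 under library totals. Among them ELOVL2, a fatty acid elongase, fell by 1.08 and STC2, a secreted glycoprotein, rose by 2.03.

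Markers of other cell types were sparse. In the Mueller glia list, 4 of 15 genes were measured, 2 rose and 0 fell, and in the fibroblast, endothelial and blood list 2 of 18 were measured, 1 rose and 0 fell (the same counts adjusted over the list alone in both). The glial gene GLUL, glutamine synthetase, read mostly through a noncoding isoform, rose by 1.43 ± 0.15 (SE), and APOE, an apolipoprotein, had 15 and 2 against 32 and 25 counts. The APOE log2 fold change of 1.43 lost its call without DMSO replicate 2 (0.57) and without BPA replicate 1 (1.23). That call was also lost with DESeq2, without a filter on low counts and on FPKM. Without DMSO replicate 1 the value was 3.52. VWF, an endothelial gene, had 74 and 67 against 118 and 118 counts (log2 fold change 0.44, adjusted p = 0.0484). This call was lost with DESeq2, without a filter on low counts and on FPKM. It was also lost without DMSO replicate 2 (0.31), BPA replicate 1 (0.43) or BPA replicate 2 (0.47). Retinal pigment epithelium genes rose in 2 and fell in 1 of 6 measured members (the same counts adjusted over the list alone; camera adjusted p = 0.618), with RPE65, the visual cycle isomerase, up by 0.94 and DCT, a melanin enzyme, down with a log2 fold change of -0.71.

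Because the deposited values are per transcript, transcripts were also tested one by one, a comparison added after the data were seen. Of 17418 transcripts, 3877 were higher and 3943 lower in BPA. Retained-intron transcripts, which keep an intron that other isoforms of the gene remove, rose in 1452 of 4834 and fell in 504, whereas protein-coding transcripts rose in 1335 of 7036 and fell in 2180. Within 799 genes with enough reads of both kinds, retained-intron reads rose more than protein-coding reads in 360 and less in 64 (interaction test, adjusted p under 0.05), with a median difference of 0.55 on the log2 scale. In HDAC2, a histone deacetylase gene named here after its values were seen, that difference was 3.23 ± 0.21 (SE). PCBP2, an RNA-binding protein gene singled out in the same way, went the opposite way with -1.69 ± 0.17 (SE). HNRNPD, another RNA-binding protein gene chosen after its values were seen, had 211 and 221 protein-coding reads in DMSO and 70 and 77 in BPA, against 295 and 335, and 827 and 893 retained-intron reads. The transcript counts were 1287 higher and 1635 lower with DESeq2 and 7371 and 1660 under library totals.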

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

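The sums over transcript classes and every transcript setting were chosen after seeing the data. Genes higher and lower in BPA, 2750 and 2832, moved by over 1.5 times with DESeq2 (1268 and 1263, of which 1268 and 1260 were among the main calls), library totals only (5080 and 1251), unfiltered log2(FPKM + 1) (227 and 305), glmTreat at 1.5-fold (1095 and 1068) and protein-coding transcripts only (1528 and 1512, where fewer genes were tested). DESeq2 was run on all genes with a count, so test and filter changed together, and the cause was not tested for it or for FPKM. Library totals shift every gene by about the same amount, and glmTreat asks for a larger change. Leaving out each library gave 1950 to 2686 higher and 1964 to 2824 lower. The lowest counts came without BPA replicate 1, and a lone library is then assumed to vary like the other group.

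Transcripts, 3877 and 3943, became 1287 and 1635 with DESeq2, 7371 and 1660 under library totals, 706 and 1077 with no filter, 2090 and 2034 at 50 counts or more, and 1893 and 1751 with glmTreat. The cause was not tested for DESeq2 and the filters. Leaving out each library gave 2485 to 3576 higher and 2820 to 3856 lower, with 2485 without BPA replicate 1. Of the 6 lists past camera, 0 passed with an estimated correlation and 6 of the 19 past fry, which does not compare a list with other genes. Without retained-intron transcripts 11 passed, the cause of which was not tested, and leaving out each library gave 7 to 9, the 6 among them each time.

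Over 2649 comparisons of 151 named genes, 2453 kept direction and side of the threshold, 190 lost the call, 1 gained it (ESR2) and 5 changed sign. FTL (0.059), PARP1 (0.0054) and ATP6V1A (0.0379) changed sign under library totals, within the 0.41 shift of all genes. ATP5F1A changed sign with protein-coding transcripts only (-1.10) and without retained-intron transcripts (-0.52), where its retained-intron reads are left out. Unfiltered FPKM ended 91 of the lost calls.

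A replicate block gave 2835 and 2925 genes, 3747 and 3910 transcripts and 8 lists, the 6 with immediate early genes (adjusted p = 0.0263) and nuclear noncoding RNAs (0.0449) added, and ended no call of a named gene. The labels do not say that replicate numbers pair libraries, and the correlation of same-numbered deviations was 0.061 across all 12063 genes and 0.224 across the 4195 with a mean count of at least 100. With 2 pairs this leaves pairing open.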

Other observations

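None of the further fixed gene groups passed where camera was run, while 22.8% of all tested genes rose and 23.5% fell. Nuclear noncoding RNAs rose in 5 of 7 measured members and fell in 0 (camera adjusted p = 0.0740, and 0.503 with an estimated correlation). The list passed camera without retained-intron transcripts (adjusted p = 0.0345) and with a replicate block (0.0449). It also passed without DMSO replicate 2 or without BPA replicate 1. NEAT1 and MALAT1, both long nuclear RNAs, were up by 0.86 and 0.93. Among p53 targets 7 of 17 rose and 2 fell (adjusted p = 0.0871; without BPA replicate 2 0.0435, in a range of 0.0435 to 0.609), with TIGAR, a regulator of glycolysis, up by 1.96 and ZMAT3, an RNA-binding protein gene, up by 1.44, while MDM2, the p53 ubiquitin ligase, had a log2 fold change of -0.83. BCL2 family and caspase genes rose in 4 and fell in 3 of 9 (adjusted p = 0.618), with a mean of 0.28 and a median just under 0 that was 0.41 under library totals. There HRK, which promotes cell death, rose by 1.27 and CYCS, cytochrome c, fell by 0.76. Hypoxia and glycolysis genes rose in 6 and fell in 5 of 24 (7 and 5 adjusted over the list alone; adjusted p = 0.618), with PGAM1, a glycolytic mutase, down by a log2 fold change of -1.49. Under library totals 12 of that list rose and 2 fell (median 0.18, and 0.59 under library totals). With protein-coding transcripts only, 1 of 13 rose and 3 fell. VEGFA, the angiogenic factor, rose by 1.60 with 99.4% of its reads in retained-intron transcripts. Cytosolic ribosomal protein genes rose in 13 and fell in 4 of 43 (11 and 4 adjusted over the list alone; adjusted p = 0.115), and 26 of the 43 were read mostly through retained-intron transcripts. With protein-coding transcripts only, 6 of 25 rose and 6 fell (median 0.06), while under library totals 27 of the 43 rose and 2 fell. Synapse genes rose in 6 and fell in 7 of 18 (adjusted p = 0.344; median -0.20, and 0.21 under library totals), with CHGB, a granin of secretory granules, down by a log2 fold change of -1.35. WNT pathway genes rose in 3 and fell in 6 of 12 (adjusted p = 0.358; median -0.29, and 0.12 under library totals), with the WNT inhibitor gene APCDD1 at -1.72 and the receptor gene FZD7 at 1.07.

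In the other lists the rises and falls were 2 and 4 of 14 for fatty acid synthesis (adjusted p = 0.618), 3 and 0 of 6 for liver X receptor targets (0.342), 3 and 4 of 15 for NRF2 targets (0.985) and 2 and 8 of 20 for DNA damage repair (0.484). They were 2 and 4 of 10 for other retinal neurons (0.484), 6 and 2 of 13 for adhesion and matrix (6 and 3 adjusted over the list alone; 0.625) and 4 and 2 of 18 for autophagy (3 and 1 adjusted over the list alone; 0.600). Lists with under 5 measured genes gave 1 and 0 of 2 for metallothioneins, 2 and 1 of 4 for xenobiotic metabolism and 1 and 0 of 4 for NF-kB and interferon. Where no second pair is given, the counts were the same adjusted over the list alone. Under library totals 13 of the 36 list medians changed sign, among them those of fatty acid synthesis (-0.12 to 0.29), NRF2 targets (-0.08 to 0.33), DNA damage repair (-0.26 to 0.15) and adhesion (-0.04 to 0.37). For the NRF2 and adhesion lists the mean, 0.07 and 0.24, and the set test pointed up while the median lay under 0.

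Of the tests below, those on GC content and on olfactory receptor genes were set before their results were seen, and all others after, including the bounds on tailless RNAs and on sense-intronic transcripts, which were made stricter once results were known and left both explanations open. The heat shock rise was weighed first. It was not only a gain of noncoding isoform reads, since the median log2 fold change of the members was 1.71 with protein-coding transcripts alone, nor only sharing between HSPA1A and HSPA1B, since the other members had a median of 2.08. For HSP90AA1 itself the rise may come from intron-containing and other noncoding isoforms, because its protein-coding transcripts gave 0.27 ± 0.26 (SE) against 4.42. They held only 4.05% of its reads, and bases shared by isoforms seem not to be counted. Whether its coding mRNA rose is therefore left open. A response of the cells to BPA remains an untested hypothesis, and the dose unit in the labels is open.

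The fall of the mitochondrial mRNAs was weighed second. Scaling alone does not account for it: under library totals the smallest of the 13 falls was still -0.85 ± 0.07 (SE), that of MT-ND6. An equal loss of all mitochondrial RNA is argued against by MT-RNR1, which lay 1.45 above the median of the mRNAs. MT-RNR2, which had many more counts, was closer to that median of -1.64, at -0.82 ± 0.08 (SE). A weaker recovery of RNAs with short or no poly(A) tails could still contribute, since histone mRNAs, which lack such tails, also fell. The 43 tested genes of tailless RNA types had a median of 0.33, but only 3 had a mean count of 100 or more, all of them copies of 7SL RNA, so this explanation and an effect of BPA on mitochondrial transcripts cannot be told apart.

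The gain of retained-intron transcripts was weighed last. After trends with GC content, length and abundance were removed, retained-intron transcripts still lay 0.43 above protein-coding ones, against 0.49 before. Genomic DNA or an even background is argued against by 381 olfactory receptor genes, whose reads per base did not gain (-0.012 of the gain over retained-intron transcripts). An even gain of RNA from all introns, as unspliced or nuclear RNA would give, stays open: retained-intron transcripts exceeded 142 sense-intronic transcripts by 0.24, with a 95% bootstrap interval from 0.0028 to 0.408 that nearly reaches 0. A change in splicing or in decay of intron-containing RNA in BPA-treated cells is a hypothesis that these data did not separate from that gain.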
